A study of Homo sapiens with 4 samples.

How the data were processed

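Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers DNA bound by a protein with an antibody, and places where many sequenced fragments pile up are called peaks. The assay was run in LNCaP, an androgen-sensitive human prostate cancer cell line, after vehicle or GSK2879552, an inhibitor of the histone demethylase LSD1 (KDM1A). Per the labels' protocols, cells were maintained in medium with 10% fetal bovine serum, moved to 5% charcoal-stripped serum and exposed to 50 µM of the drug for 4 h, and libraries were made with a ThruPLEX kit. The labels disagree on the antibody target: the titles name FOXA1, whereas the antibody field and the design text name FOXA2. Both are forkhead pioneer factors, and the peaks are called FOXA peaks here because the lists cannot settle which protein was precipitated.

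The 4 samples were 2 lanes for each of the 2 conditions, which the labels call technical replicates. The descriptions of both lanes of a condition name the same list, so each condition had 1 pooled peak list and no replicate spread. The submitters' processing notes name BWA 0.7.2, SAMtools 0.1.18, MACS2 2.1.2 and the hg19 (GRCh37) build, while the calling settings, read filters and any control library are not given in the sources used here. For each peak the authors deposited a fold enrichment over local background at the summit, a −log10 p and a −log10 q at the summit, and a whole-number score. The deposited score lay within 1 of 10 times the −log10 q, rounded down, in 100% of the peaks of both lists, and was not used further. These values are the authors' own. As deposited, they served here to describe, rank or filter the peaks of each list, and their medians and the lists left by a common threshold are given side by side. Fold and −log10 values depend on depth, so signal at a site was compared between lists only through the pileup and background solved from them. The −log10 p of weak GSK2879552 peaks also set the thresholds for the share expected from depth. The deposited offset of the summit from the peak start gave summit positions. Coordinates are hg19, counted from 1.

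Relative depth was read from the lists. MACS2 writes a fold enrichment as pileup plus 1 over background plus 1, and a p from a Poisson distribution with that background. Solving the deposited fold and −log10 p for a whole-number pileup (fragments over the summit) and a background succeeded in 100% of the peaks of both lists, with a tolerance of 0.001 on the −log10 p. The background never fell below a floor, which was 1.53 fragments in the vehicle list and 0.364 in the GSK2879552 list. Their ratio of 0.238 scaled vehicle pileups to the GSK2879552 depth. The shortest peak, which MACS2 sets to the fragment length, was 181 bp with vehicle and 164 bp with GSK2879552. With these lengths the floors give a read number 3.81 times higher with vehicle, provided both lists were called with the same genome size. The read totals themselves depend on that setting, which is not given in the sources used here, and are not printed. Background above the floor came in whole steps of 1 fragment in a 10-kb window in 100% of peaks, with a tolerance of 0.05 step, as when calling is run without a control library. In that case a strong peak raises its own background, and its fold enrichment is compressed. The highest pileup was 356 fragments with vehicle and 322 with GSK2879552, just under 362 and 328, which equal 2 fragment lengths each and the ceiling that removal of duplicate reads sets. Duplicate handling is not given in the sources used here. As an alternative chosen after the data were seen, pileups were corrected for that ceiling, taking fragment starts as evenly spread.

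A vehicle peak counted as overlapped if it shared at least 1 bp with a GSK2879552 peak, and the reverse. Vehicle peaks were ranked by −log10 q and split into 10 equal deciles and 100 equal classes. The share expected at a class mix was the average over those 100 classes, weighted by the peaks of a chromosome or place. The share expected from depth alone was the Poisson probability that a vehicle peak, at its scaled pileup and background, would still reach a −log10 p of 3.76 (the weakest GSK2879552 peak), 4.89 (the boundary of the weakest 1%) or 6.24 (the boundary of the weakest decile). This treats the observed pileup as the true rate. Shares carry Wilson 95% intervals, which cover counting error only, because neither lanes nor peaks are biological replicates. For the same reason no p-value between conditions is given.

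The peaks named in the text were fixed before the data were examined as the 5 with the highest −log10 q in each of 3 classes: vehicle peaks overlapped, vehicle peaks not overlapped, and GSK2879552 peaks not overlapped. The named windows were the 3 windows of 1 Mb with the most peaks in each list. The same rule would have named genes from 11 gene lists fixed in advance: androgen response, luminal identity, basal epithelium, cell cycle, LSD1 complex, neuroendocrine, liver, blood, stroma, housekeeping and forkhead family. These lists, promoter shares and forkhead motif shares were not analysed here, because they need an hg19 annotation or sequence and the gene table used here has another build. No gene names are therefore attached to peaks.

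Alternatives covered stricter −log10 q and fold thresholds, the sequences counted, merging of close peaks, the definition of overlap, equal list lengths, the measure of strength and thinning to equal depth. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The pileup solution was tested on 20000 simulated peaks resembling each list and recovered 100% of the pileups. In simulated lists at the lower depth, the predicted number of called peaks was 0.998 of the simulated number with no drop in signal and 1.025 of it with a factor of 0.5. These lists were drawn by the same Poisson rule as the prediction, with background at the floor, so they check the arithmetic only. In the data, the variance of GSK2879552 pileups at overlapped peaks of the strongest decile was 9.82 times the Poisson value.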

Results

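FOXA peaks were mapped in LNCaP prostate cancer cells after vehicle and after 4 h of 50 µM GSK2879552, with 1 pooled peak list per condition. FOXA factors open chromatin at enhancers that the androgen receptor also uses, and LSD1 is a demethylase found at such enhancers. The comparison asks where FOXA binding is seen with and without the LSD1 inhibitor. The antibody target is given as FOXA1 in some labels and FOXA2 in others. Read from the lists, the vehicle library was deeper, with a background floor 4.21 times that of the GSK2879552 library. The number of reads kept for calling was 3.81 times as high, provided both lists were called with the same genome size.

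The vehicle list held 149340 peaks and the GSK2879552 list 28485, a ratio of 5.24. Vehicle peaks covered 51.2 Mb of the genome and GSK2879552 peaks covered 6.61 Mb. The median vehicle peak was 316 bp wide (interquartile range 239 to 416) and the median GSK2879552 peak 214 bp (172 to 270). The median −log10 q was 12.4 with vehicle and 6.41 with GSK2879552, and the median fold enrichment was 6.98 and 6.46, all as the authors' caller gave them. Scaling by depth alone would have left between 61579 and 95604 of the vehicle peaks, depending on the calling threshold assumed, or 2.16 to 3.36 times the GSK2879552 list. The ratio was 10.9 among peaks with a −log10 q of at least 10, and 3.41 or 2.13 after vehicle pileups were thinned to the GSK2879552 depth, depending on the p required. The values of 2.16 and 2.13 hold only the vehicle peaks to a −log10 p of 6.24. They still count every GSK2879552 peak, including the weakest decile, which lies below that p.

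By an overlap of at least 1 bp, most GSK2879552 peaks lay on vehicle peaks, and most peaks of the longer vehicle list had no GSK2879552 counterpart. Of the GSK2879552 peaks, 25966 (91.2%, 95% interval 90.8 to 91.5) overlapped a vehicle peak and 2519 did not. Of the vehicle peaks, 25780 (17.3%, 17.1 to 17.5) were overlapped and 123560 were not. When a list was shifted by 50, 100 or 200 kb, the overlapped share was 3.17% to 3.67% for GSK2879552 peaks and 0.603% to 0.6997% for vehicle peaks. At overlapped peaks the summits of the lists lay a median of 26 bp apart, and 93.1% were within 100 bp. With a reciprocal overlap of 0.5, 48.7% of GSK2879552 and 9.28% of vehicle peaks were overlapped, a rule that a narrow peak inside a wide one can fail. With summits within 200 bp the values were 89.0% and 17.0%. Among equal numbers of top peaks, 61.3% of vehicle peaks were overlapped, and among the top 1000 of each list 23.7% of either. Thinning the vehicle list to equal depth gave 24.7% at the weakest p, and 35.6% at a stricter p chosen after the data were seen.

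The share of vehicle peaks overlapped fell with peak strength. It was 79.7% (79.1 to 80.4) in the strongest decile, 39.5% in the next, 19.9% in the third and 1.12% (0.962 to 1.30) in the weakest, with 14934 peaks in each. The strongest 1% was overlapped almost completely, at 1488 of 1494 peaks (99.6%, 99.1 to 99.8). The strongest decile supplied 11908 overlapped peaks, 46.2% of the total, and the strongest 20% supplied 69.1%. By the Poisson rule for the lower depth alone, with the strictest of the 3 thresholds, 99.8% of the strongest decile, 94.4% of the next, 76.5% of the third and 2.86% of the weakest would have been called. The overlapped share was below that value in every decile. With a reciprocal overlap of 0.5 the strongest decile was overlapped at 41.0%, and with summits within 200 bp at 79.1%. The reciprocal rule can fail on width alone, since the median width was 489 bp in this decile and 214 bp in the GSK2879552 list. With strength ranked by fold enrichment the weakest decile was overlapped at 3.21%.

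**Figure D1:**
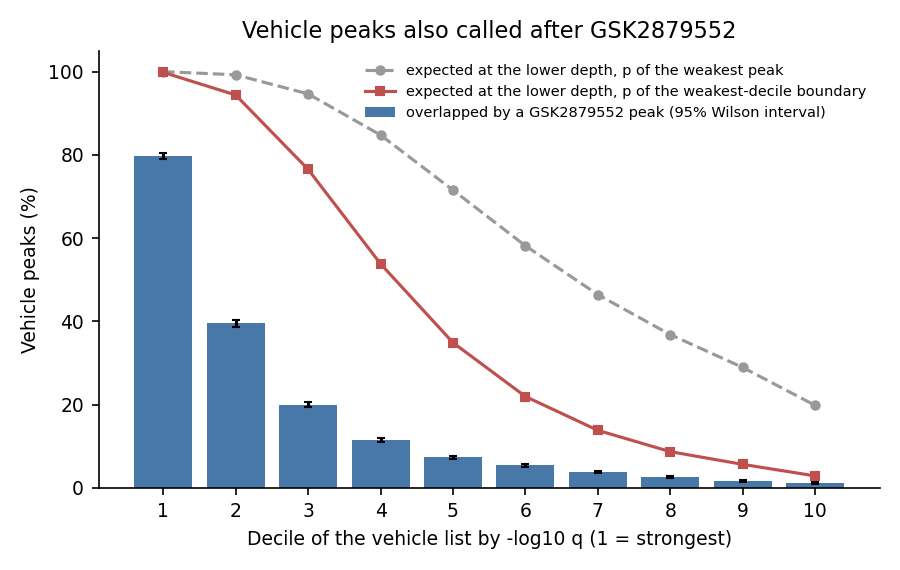
Share of vehicle peaks (percent) overlapped by a GSK2879552 peak in each decile of the vehicle list by −log10 q, with 95% Wilson intervals (bars), beside the share expected at the lower depth under the laxest and strictest of 3 calling thresholds (lines). The bars fall from 79.7% to 1.12% and lie below both lines in every decile.

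Pileups at the strong shared peaks were lower with GSK2879552 than depth scaling gave. In the strongest decile the median GSK2879552 pileup was 12 fragments against 24.5 for the depth-scaled vehicle pileup, with a median ratio of 0.485 (log2 −1.04, interquartile range −1.42 to −0.58). The GSK2879552 pileup was below the scaled value in 89.2% of these 11908 peaks. In the strongest 1% the median ratio was 0.521 (log2 −0.94, −1.34 to −0.51), and 87.6% of the 1488 peaks were below the scaled value. Ratios in weaker deciles were not read, because a weak vehicle peak enters this comparison only if its GSK2879552 pileup was high enough to be called. The same selection removes low ratios from the strongest decile, where 79.7% of peaks enter. Ranking by vehicle signal works the other way, since it picks peaks for high vehicle pileup and so lowers their ratios by an unknown amount. Of the top 1000 peaks of the GSK2879552 list, picked for GSK2879552 signal, 893 had a ratio of at least 1. The size of the drop therefore depends on which list did the ranking. The highest pileups, 356 fragments with vehicle and 322 with GSK2879552, approach the ceiling of 362 and 328 that removal of duplicate reads sets, and correcting for it lowered the median ratio to 0.412 in the strongest decile and 0.374 in the strongest 1%.

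**Figure D2:**
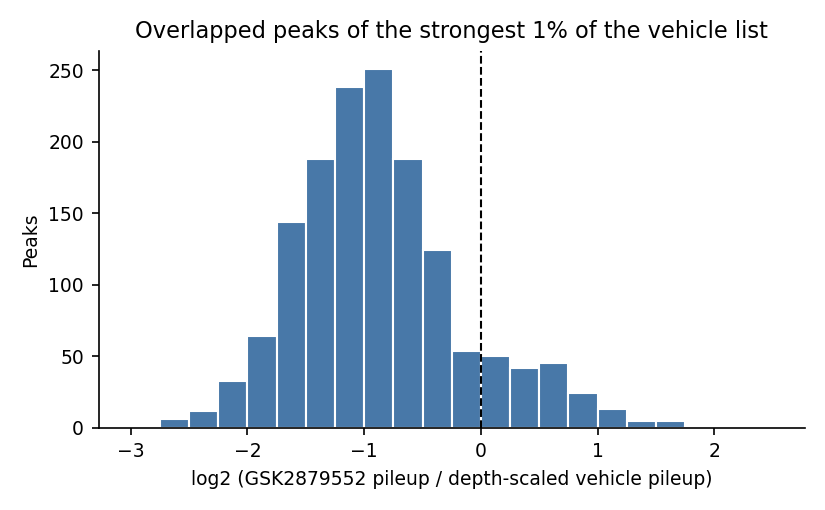
Number of overlapped peaks in the strongest 1% of the vehicle list against the log2 ratio of GSK2879552 pileup to depth-scaled vehicle pileup, in steps of 0.25. Most peaks lie left of the dashed line at equality, with a median of −0.94, and 185 of the 1488 lie at or right of it (111 after correction for the duplicate ceiling).

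The 5 strongest shared peaks lay on either side of the depth-scaled value. The top vehicle peak, on chromosome 18 from 70856819 to 70857426, had a pileup of 319 fragments, or 75.8 after scaling, and a GSK2879552 pileup of 44, a ratio of 0.580. The peak on chromosome 10 from 110481521 to 110482231 had a ratio of 0.799, with a GSK2879552 pileup of 60. On chromosome 8 from 71863446 to 71864059 the ratio was 0.722, and on chromosome 10 from 98430543 to 98431120 it was 0.880. The peak on chromosome 18 from 33429210 to 33429706 went the other way, with a scaled vehicle pileup of 63.0, a GSK2879552 pileup of 113 and a ratio of 1.79. Corrected for the duplicate ceiling, these 5 ratios were 0.258, 0.373, 0.375, 0.489 and 1.22, in the order named.

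Some strong vehicle peaks had no GSK2879552 peak. The strongest lay on chromosome 18 from 6835253 to 6835811, with a pileup of 195 fragments, 46.3 after scaling, at rank 321 of the vehicle list. Its nearest GSK2879552 summit was 53.6 kb away. On chromosome 10 from 12762372 to 12763085 the scaled pileup was 42.5, with the nearest GSK2879552 summit at 30.6 kb. The next were on chromosome 13 from 25807872 to 25808365 (scaled pileup 35.9, nearest summit 9.23 kb), chromosome 5 from 38783006 to 38783526 (37.8, 38.4 kb) and chromosome 6 from 37230372 to 37230895 (37.6, 90.5 kb). The lists give no GSK2879552 pileup at these sites, since a place without a called peak has no entry.

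Peaks seen only in the GSK2879552 list were mostly weak. Their median pileup was 6 fragments, against 10 for the overlapped GSK2879552 peaks, and their median width was 164 bp, the shortest the list holds. Of the 2519, 3 were in the strongest decile of the list and 804 in the weakest. A vehicle summit lay within 1 kb of 322 of them (12.8%), and the median distance was 6.62 kb. The strongest was on the unplaced sequence chrUn_gl000220 from 118287 to 118578, with a pileup of 242 over a background of 64.6, a fold of 3.70 and a vehicle summit 0.476 kb away. Scaled to the vehicle depth its pileup would be 1018, above the duplicate ceiling of 362 in that list, so the vehicle list could hold no comparable pileup. The next lay on chromosome 8 from 99935974 to 99936237 (pileup 28, vehicle summit 0.473 kb away), chromosome 19 from 16985883 to 16986164 (27, 3.11 kb), chromosome 10 from 38888604 to 38888879 (28, 1.17 kb) and chromosome 7 from 61980384 to 61980646 (55, 1.19 kb). Of these 5, the sites on chrUn_gl000220 and on chromosomes 10 and 7 lay on unplaced sequence or within 1 Mb of a long stretch without peaks.

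The overlapped share was low on each of chromosomes 1 to 22 and X. Among chromosomes 1 to 22 and X, the overlapped share ran from 14.2% on X (13.1 to 15.2) to 19.7% on chromosome 16 (18.4 to 21.1). X also had the fewest vehicle peaks per Mb, 27.6, against 57.8 on chromosome 3. The ratio of vehicle to GSK2879552 peaks was 4.47 on chromosome 16 and 6.20 on X. Given the strength of its peaks, X was expected to have 13.9% overlapped, and chromosome 16 lay 1.74 percentage points above the share given by strength. The Y chromosome stood apart, with 22.5% of its 908 vehicle peaks overlapped (19.9 to 25.3) against 12.7% expected from their strength. Part of this came from the window from 13 to 14 Mb, which held 67 of its vehicle peaks and 42 of its 204 overlapped peaks.

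**Figure D3:**
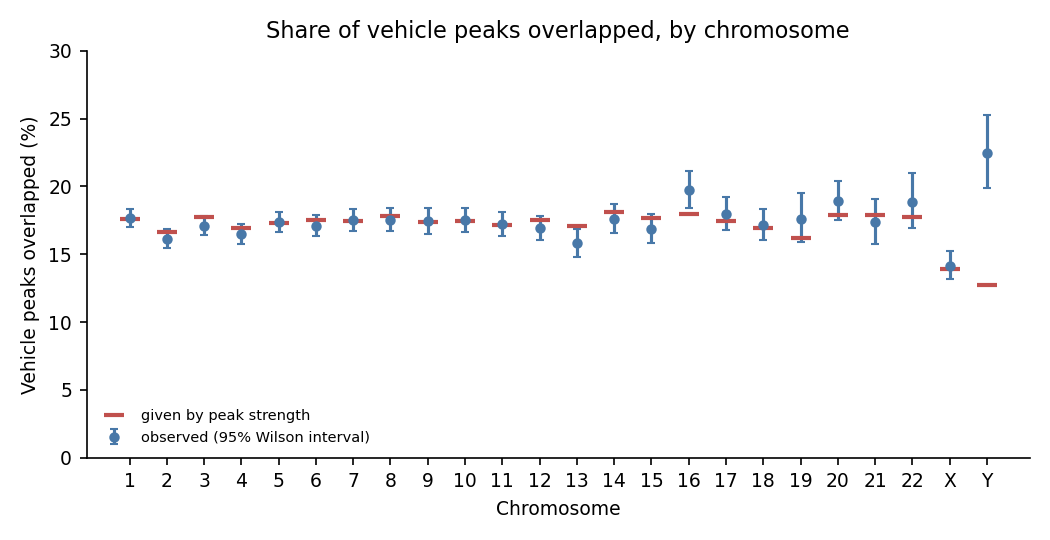
Share of vehicle peaks (percent) overlapped by a GSK2879552 peak on each chromosome, with 95% Wilson intervals (points), beside the share given by the strength of its peaks (dashes). Chromosomes 1 to 22 and X lie between 14.2% and 19.7%, and Y lies at 22.5% against 12.7% by strength.

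Peak numbers per 1-Mb window followed each other across the lists (Spearman rho 0.725 over 2916 windows, which are not independent replicates), but the 3 richest windows differed. The windows with the most vehicle peaks were on chromosome 21 from 17 to 18 Mb (136 vehicle and 29 GSK2879552 peaks, 19.1% of vehicle peaks overlapped), chromosome 12 from 81 to 82 Mb (115 and 29, 24.3%) and chromosome 11 from 23 to 24 Mb (114 and 26, 21.1%). The windows with the most GSK2879552 peaks were on chromosome 10 from 42 to 43 Mb (60 and 51 peaks, 71.7% overlapped, 59.2 to 81.5), Y from 13 to 14 Mb (67 and 51, 62.7%) and chromosome 4 from 49 to 50 Mb (60 and 43, 58.3%). The windows on chromosomes 10 and 4 border long stretches without peaks, from 39151198 to 42356093 and from 49659871 to 52719419, the kind of place where reads gather on repeats that a genome build under-represents. Across the 2916 windows with vehicle peaks, the median was 52 vehicle and 9 GSK2879552 peaks, and 16 windows had no GSK2879552 peak.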

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

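Thinning to the p of the weakest-decile boundary and the correction for the duplicate ceiling were chosen after seeing the data; the other alternatives were fixed before the data were examined. In each alternative with unequal list lengths the vehicle list stayed longer, and 16 alternative values stayed within the counting interval or, for peak numbers, within 1.5 times, while 31 moved, those for chromosomes 1 to 22 and X among the 16. The 16 also include the peak numbers and their ratio with every summit row counted, which could not move because no region had more than 1 row. With a −log10 q of at least 5, the ratio of peak numbers was 6.94, with 13.8% of vehicle and 95.8% of GSK2879552 peaks overlapped. At 10, 85991 and 7924 peaks were left, with a ratio of 10.9 and 8.97% and 97.6% overlapped. With a fold of at least 5 the values were 4.81, 19.1% and 92.4%. Merging peaks within 500 bp gave a ratio of 5.03. Reciprocal overlap of 0.5 gave 9.28% and 48.7%, with 41.0% of the strongest and 0.797% of the weakest vehicle decile. Summits within 200 bp gave 17.0% and 89.0%. Equal numbers of top peaks gave 61.3% and 61.8%, and the top 1000 of each list gave 23.7% for both. Ranking by fold gave 74.5% in the strongest and 3.21% in the weakest decile. Thinned to the GSK2879552 depth, the ratio was 3.41 with 24.7% of the remaining vehicle peaks overlapped at the weakest p, and 2.13 with 35.6% at the weakest-decile p. The ratio of 2.13 still counts the GSK2879552 peaks below that p. Corrected for the duplicate ceiling, the median pileup ratio was 0.412 in the strongest decile and 0.374 in the strongest 1%, where 111 ratios were at least 1. For settings other than the thinning and this correction, why the values moved was not tested. No paired analysis was possible because each condition had 1 pooled list. The planned promoter, motif and gene-list results were not run for want of an hg19 reference. The lower depth of the GSK2879552 library limits what can be said of weak vehicle peaks.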

Other observations

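The tests of depth alone, of a single drop at every site and of nearness to the calling threshold were chosen after the results they measure had been seen, and no test of the quality of the immunoprecipitation was possible. The places and peak classes in the next 2 paragraphs were chosen after the peak numbers were seen, while the bounds of the depth-ratio test that uses such places were set before its pileup ratios were seen.

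Some of the strongest sites had a GSK2879552 pileup at or above the depth-scaled vehicle pileup. In the strongest 1% of vehicle peaks, 185 of 1488 overlapped peaks (12.4%, 10.9 to 14.2) had a ratio of at least 1, and 24 of them a ratio of at least 2. Corrected for the duplicate ceiling, 111 had a ratio of at least 1 and 16 a ratio of at least 2. The spread of this ratio between libraries of one condition is unknown. The median vehicle width was 548 bp in the 185 and 549 bp in the 1303 other peaks. Of the top 1000 peaks of the GSK2879552 list, 999 overlapped a vehicle peak, 893 had a ratio of at least 1, a value raised by picking them for high GSK2879552 signal, 819 lay in the strongest vehicle decile and 237 in the vehicle top 1000.

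Regions around long stretches without peaks kept more of their peaks than strength alone gave. Within 1 Mb of the longest such stretch of each chromosome there were 2115 vehicle and 784 GSK2879552 peaks, a ratio of 2.70 against 5.35 over the rest of the genome outside Y and unplaced sequence. In these regions 31.2% of vehicle peaks were overlapped (29.2 to 33.2), against 15.7% expected from their strength. Unplaced, unlocalised and haplotype sequences showed 28.9% (25.9 to 32.1) against 14.4%. That class was mixed: 32 of 44 vehicle peaks were overlapped on chr9_gl000199_random and 24 of 50 on chrUn_gl000225. On haplotype sequences it was 4 of 46 on chr6_cox_hap2 and 20 of 64 on chr17_ctg5_hap1. The rest of Y showed 21.9% (19.2 to 24.9) against 12.9%, with 42 of its 180 overlapped peaks in the window from 13 to 14 Mb. Unplaced sequences and regions beside such stretches are known to gather reads from repeats that a genome build under-represents.

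The GSK2879552 list had fewer and weaker peaks. Depth alone with Poisson spread is argued against at the depth ratio read from the background floors. The strongest decile was overlapped at least 20.1 percentage points less often than that rule gave under each of the 3 thresholds. The spread in the data was wider, with a variance of GSK2879552 pileups 9.82 times the Poisson value at overlapped peaks of this decile. How far a wider spread at the lower depth would by itself reduce the share called was not tested. A single drop at every site on top of depth stays open. Fitted to the overlapped share of the strongest decile, it predicted 16578, 12637 and 9857 overlapped peaks in the other deciles, from the laxest threshold to the strictest. The observed number was 13872, so the direction of the difference changed with the threshold. With uncalled peaks placed lowest, the median ratio fell from 0.518 (0.506 to 0.535) in the strongest 1% to 0.366 (0.332 to 0.391) in the last 1% of the strongest decile, 1.42 times apart. The duplicate ceiling alone can give such a trend, and corrected for it the medians were 1.12 times apart. A wrong depth ratio also stays open: on unplaced, haplotype and mitochondrial sequence and beside the long stretches without peaks, the median pileup ratio in the strongest decile was 0.645 over 222 peaks, against 0.483 elsewhere, and 0.552 against 0.411 after correction for the duplicate ceiling, gaps just outside and just inside the 0.15 set as the bound for a wrong ratio. Poorer immunoprecipitation of one library and an effect of LSD1 inhibition on FOXA binding cannot be told apart with 1 library per condition, and either may contribute.

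Peaks found only in the GSK2879552 list may be mostly peaks near the calling threshold. Of these, 67.6% (65.8 to 69.4) were in the weakest 3 deciles of their list. This uses the same ranking that had shown them to be weak, so it is no separate support. Unplaced, haplotype and mitochondrial sequences held 2.14% of them, a test that decides nothing, because all 294 GSK2879552 peaks there would make at most 11.7%. The share of GSK2879552 peaks without a vehicle peak was 18.4% on unplaced and haplotype sequences and 14.3% beside the long stretches without peaks, against 8.56% on the rest of chromosomes 1 to 22 and X, and 3 of the 5 strongest lay in such places. Binding gained under the inhibitor was not tested.

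Chromosomes differed in the share of vehicle peaks overlapped, and differences in peak strength may account for part of this. Over chromosomes 1 to 22 and X the standard deviation of the share was 1.10 percentage points, and 0.743 after subtracting the share given by strength, which is 0.676 of the first. That lies between the bounds set in advance for and against strength as the main source, so the question stays open. The remainder ran from −1.25 points on chromosome 13 to 1.74 on chromosome 16. No biological explanation was tested.

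A hypothesis that FOXA sites with close neighbours are overlapped more often, beyond their strength, was tested and not borne out. Whether neighbouring peaks are kept or lost jointly was not tested. Vehicle peaks with another vehicle peak within 10 kb were overlapped in 16.6% of 104126 cases, and isolated peaks in 18.8% of 45214. At equal strength the difference was 0.119 percentage points in favour of peaks with neighbours, inside the range of −0.558 to 0.566 given by 1000 shuffles.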
